A study of Arabidopsis with 12 samples.

How the data were processed

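RNA was measured in 12 libraries of Arabidopsis seedlings, 3 each of WT control, WT 3 days, mutant control and mutant 3 days, grouped by their titles, with the mutant taken to be mac3a3b as the series text names it. Per the labels' protocols, total RNA of seedlings was enriched for polyadenylated RNA with oligo dT and made into libraries with an Illumina TruSeq kit. Per the submitters' notes, RSEM and the TAIR10 build were used. Versions, aligner, read length, strand setting and filters are not given in the sources used here. The authors deposited 1 table of the series with TPM for 37825 genes in each library, with gene length, group means, annotation columns and KEGG pathways. Per the labels and the table, TPM is a share of each library scaled to a fixed total and length-corrected by the authors. It gives neither depth nor a counting interval. A rise of a few abundant classes lowers all other values in the same library, and RSEM can divide reads between near-identical copies, whose values are uncertain. All sample columns were used, but not the authors' group means. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

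Loci were matched to symbols by locus identifier through a RefSeq gene table: 37572 rows matched, 10544 carried a symbol, 67 rows had assembler identifiers without a locus, 7082 were 0 in all libraries and 1 row was empty. No genome was used, and no coordinates are given. Replicates within a group correlated at r of 0.982 to 0.989, and at most 0.855% of genes had identical TPM above 0 in a pair of libraries, so each library counted as 1 replicate.

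The comparisons, tests, filter, gene lists, named-gene rule and all alternatives but 1 were chosen before the data were examined. Genes with a TPM of at least 1 in at least 3 of the 12 libraries were kept (22462), values were taken as log2(TPM + 1), and limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 12 libraries with an intensity trend. The 5 contrasts were mutant against WT at control and at 3 days, 3 days against control in WT and in the mutant, and the difference of those responses. P-values were adjusted by Benjamini-Hochberg over the genes kept and called at an adjusted p under 0.05, and 2-fold calls were counted too. An exact test of 1 gene with 3 against 3 libraries cannot give a two-sided p below 0.1, so spread was pooled across genes. A gene's KEGG pathways in the table were tested for enrichment by one-sided Fisher's exact tests on higher and lower calls, over 123 pathways and 6684 kept and annotated genes.

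The 30 gene lists held the targeted genes, MAC and spliceosome core, SR splicing factors, small heat shock proteins, large chaperones and co-chaperones, heat shock transcription factors, heat memory genes, ER unfolded protein response, salicylic acid defence, pattern-triggered immunity and camalexin, jasmonate, abscisic acid and dehydration, oxidative stress, photosynthesis, chlorophyll synthesis, senescence and chlorophyll breakdown, carbon starvation, anthocyanin and flavonoid, glucosinolate, circadian clock, flowering time, cell cycle and DNA replication, microRNA biogenesis, microRNA target genes, thermomorphogenesis and auxin growth, markers of root, guard cell lineage, vascular tissue and seed, and reference genes. Some genes stand in more than 1 list, such as SEN1 and HSP21. The list of heat shock transcription factors (17 HSF genes among its tested members) also holds DREB2A, DREB2B and DREB2C, factors of another family that act in drought and heat, and the coactivator MBF1C, and the HSF genes were counted apart after the results were seen. Lists with at least 5 kept members (28) were tested in each contrast with camera, which compares a list with all other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg over the lists. Camera with a correlation estimated from the residuals called none of the 140 tests (19 had an unadjusted p under 0.05, and the lowest adjusted p was 0.118). Fry, which tests whether a list's genes move one way on balance and does not compare it with other genes, was run as an alternative. Counts of members are given over all genes and adjusted over the list alone.

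Genes are named by this rule: MAC3A and MAC3B always; per contrast the 6 largest increases and 6 largest decreases among genes with an adjusted p under 0.05, a mean TPM of at least 5 in the higher group, a symbol and, between 2 groups, no overlap of their libraries (which chance gives in 10% of genes for 3 against 3); and per list the 2 called members with the largest change in each direction, or the most abundant member where none was called. Reference genes are only counted. Of the list members so taken, the text gives up to 4 per list and comparison. Where a fold rests on a group with a library listed at 0, the values of that group are given per library, and such a fold depends on the pseudocount.

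The rates below, from few changed genes, may not hold for real contrasts with 49.5% to 85.9% of genes called. The fit was tested on simulated data made from the real means and spread, with 67 genes changed 1.5-fold, 67 2-fold and 66 4-fold. The fit recovered 77.6%, 95.5% and 100% of them for mutant against WT at control, 73.1%, 97.0% and 98.5% at 3 days, 82.1%, 95.5% and 98.5% for the WT response, 80.6%, 95.5% and 100% for the mutant response and 53.7%, 92.5% and 98.5% for the difference of responses. False calls made up 6.67%, 7.73%, 5.15%, 6.12% and 4.68% of all calls in the same order. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, removal of organelle genes, pair-only fits, array weights, robust moderation, the replicate number as a block, leaving out each library, and 2-fold calls for the enrichment. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 handled tables and figures. Splicing, microRNAs and isoforms were not analysed, as the table gives 1 value per gene.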

Results

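Arabidopsis seedlings of the wild type (WT) and of the double mutant mac3a3b, mutated in MAC3A and MAC3B, were compared by RNA sequencing. Their homologous proteins belong to the spliceosome-associated MOS4 complex. The labels name 2 sampling points for each genotype, a control and 3 days after a heat treatment, and the protocol mentions 37 °C. Plant age and the length of heat are not given in the sources used. The series text speaks of 0 hours after heat where the titles say control, so a control sample could be an unheated plant or the start of recovery. The 4 groups, called here WT control, WT 3 days, mutant control and mutant 3 days, hold 3 libraries each. The labels name no unheated sample taken at 3 days. A change from control to 3 days, called a response below, may therefore also reflect age, growth or the hour of sampling. So may a difference of responses between genotypes. Expression was given as TPM, each transcript's share of its library scaled by gene length, for 37825 genes. Library sums lay between 999986.2 and 999995.5, so the number of reads behind a value is unknown. TPM values below are means ± SD of 3 libraries, and log2 fold changes of TPM + 1 are given ± 1 standard error of the limma fit, a scale that understates changes of weakly expressed genes. Changes of named genes had an adjusted p under 0.05 unless another value is given.

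The number of genes at a TPM of 1 or more was 19616 to 19678 in WT control, 20963 to 21139 in WT 3 days, 19565 to 19810 in mutant control and 18310 to 18713 in mutant 3 days. The 100 most abundant genes held 31.0 ± 0.342% of the TPM in WT control, 17.57 ± 0.265% in WT 3 days, 28.4 ± 0.540% in mutant control and 20.6 ± 0.208% in mutant 3 days. The first principal component, with 70.6% of the variance, placed the control libraries of both genotypes between -115.3 and -100.6, WT 3 days between 51.38 and 53.88 and mutant 3 days between 161.3 and 163.8. Ribosomal RNA loci, whose near-identical copies share reads and are uncertain, summed to 6739 ± 580.1 TPM in WT control, 6974 ± 1137 in mutant control, 13686 ± 715 in WT 3 days and 37711 ± 3013 in mutant 3 days.

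The targeted genes were lower in the mutant at both sampling points. MAC3A (AT1G04510) stood at 34.7 ± 1.19 TPM in WT control, 9.74 ± 0.591 in mutant control, 60.4 ± 1.03 in WT 3 days and 6.12 ± 0.623 in mutant 3 days. MAC3B (AT2G33340) stood at 72.6 ± 3.33, 10.4 ± 0.415, 133 ± 4.69 and 9.44 ± 0.581 TPM in the same order. The mutant differed from WT by -1.73 ± 0.066 (adjusted p = 1.40e-08) for MAC3A and -2.70 ± 0.055 (adjusted p = 1.23e-10) for MAC3B at control, and by -3.11 ± 0.066 (adjusted p = 8.37e-12) and -3.69 ± 0.055 (adjusted p = 1.91e-12) at 3 days. In WT both genes rose at 3 days, by 0.78 ± 0.066 (adjusted p = 4.18e-07) and 0.87 ± 0.055 (adjusted p = 3.05e-08). In the mutant the residual MAC3A signal fell (-0.60 ± 0.066, adjusted p = 3.77e-06), while MAC3B did not pass over all genes (-0.12 ± 0.055, adjusted p = 0.054) and did adjusted over the list alone, where 2 of 2 genes were lower. MAC3B did pass without mutant control replicate 1 (adjusted p = 0.0355) or mutant 3 days replicate 1 (0.0445) or 3 (0.0416). Without mutant 3 days replicate 2 it changed by -0.076. The response differed between genotypes by -1.38 ± 0.094 for MAC3A (adjusted p = 9.70e-08) and -0.99 ± 0.078 for MAC3B (adjusted p = 3.29e-07). With quantile normalization the median of both genes went from -0.36 to 0.061 in the mutant. It was 0.48 in WT and -0.42 for the difference (0.38 and -0.57 with median-of-ratios scaling).

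**Figure D1:**
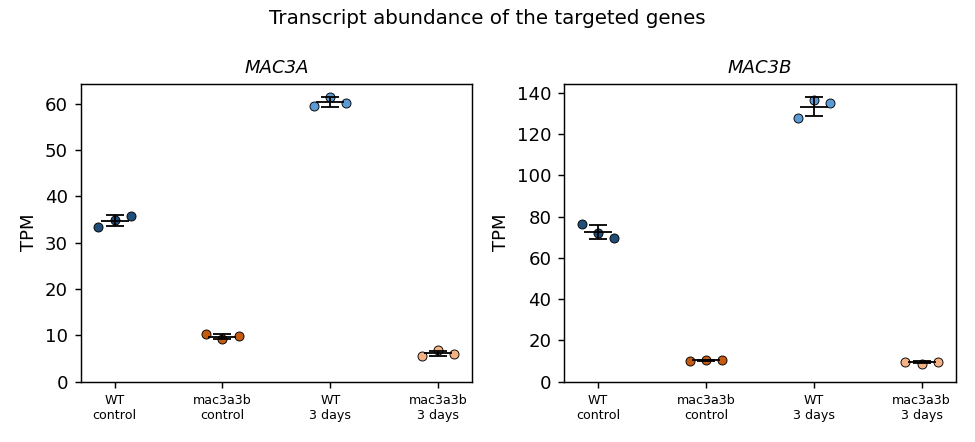
TPM of MAC3A and MAC3B in each library of the 4 groups (points, with bars of the mean ± SD of 3 libraries). MAC3B averaged 72.6 ± 3.33 TPM in WT control and 10.4 ± 0.415 in mutant control.

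The first comparison was mutant against WT in the control samples. Carbon starvation genes, which are induced when sugar is short, were lower in the mutant, with 10 of 11 members down and none up. SEN1 (AT4G35770) had 73.5 ± 21.7 TPM in WT and 7.15 ± 0.966 in the mutant, and DIN10 was lower too (-2.18 ± 0.14). Genes of anthocyanin and flavonoid synthesis were higher, with 15 of 17 up and 1 down. DFR (AT5G42800), which encodes dihydroflavonol reductase, stood at 4.56 ± 0.456 TPM in WT and 60.0 ± 4.84 in the mutant, and LDOX, the next enzyme of the pathway, was higher by 2.85 ± 0.17. Spliceosome partners of MAC3A and MAC3B were higher in 13 of 13 members, led by GFA1 (0.77 ± 0.041) and MOS4 (0.62 ± 0.051). In the aliphatic glucosinolate pathway CYP79F1, which converts chain-elongated methionine on the way to glucosinolates, went from 54.8 ± 2.91 to 144 ± 8.73 TPM.

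In all, 6803 genes were higher and 4313 lower in mutant control than in WT control (limma, adjusted p under 0.05), of which 575 and 692 changed at least 2-fold. The median of all 22462 genes was 0.060. With median-of-ratios scaling the split was 5386 higher and 5351 lower. The largest increases after the rule for named genes were SQP1 (3.61 ± 0.066), DFR (3.45 ± 0.091), ASG4 (3.34 ± 0.12), NAC044 (3.04 ± 0.12), LDOX and the iron-deficiency regulator BHLH100 (2.85 ± 0.26). SQP1, which encodes a squalene epoxidase-like protein, went from 4.8 ± 0.337 to 69.97 ± 1.78 TPM. The largest decreases were MRD1, RbcX1 (-4.0 ± 0.15), AIR1 (-3.81 ± 0.16), MEE14 (-3.43 ± 0.10), SEN1 (-3.16 ± 0.20) and MLP329 (-3.06 ± 0.15), each with an adjusted p of 4.71e-07 or less. MRD1 (AT1G53480) stood at 37.7 ± 3.75 TPM in WT control and was listed at 0 in all 3 libraries of mutant control, so no fold is given.

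Relative to the median of all genes, the carbon starvation list had a median of -1.23 (camera adjusted p = 3.97e-06, and adjusted p = 0.378 with an estimated correlation). The anthocyanin list had a median of 1.25 (camera adjusted p = 2.05e-06, and adjusted p = 0.118 with an estimated correlation). The MAC and spliceosome core list had 0.40 (camera adjusted p = 7.23e-05, and adjusted p = 0.378 with an estimated correlation). Glucosinolate genes were higher in 16 and lower in 2 of 20 members, with a median of 0.72 (camera adjusted p = 2.04e-04, and adjusted p = 0.602 with an estimated correlation). Its members included MAM3 (1.33 ± 0.14) and MYB51 (-0.47 ± 0.11). SR splicing factors were higher in 15 and lower in 2 of 20, with a median of 0.26 (camera adjusted p = 0.00137, and adjusted p = 0.378 with an estimated correlation). RSZ22A was higher (0.96 ± 0.086) and SR34B lower (-0.41 ± 0.073). Large chaperones and co-chaperones were higher in 14 and lower in 1 of 18, with a median of 0.32 (camera adjusted p = 9.95e-04, and adjusted p = 0.602 with an estimated correlation). Leading members were the organellar disaggregases CLPB4 (0.98 ± 0.062) and CLPB3 (0.96 ± 0.055). Pattern-triggered immunity and camalexin genes were lower in 10 of 15 and higher in none, with a median of -0.65 (camera adjusted p = 2.25e-04, and adjusted p = 0.378 with an estimated correlation). Among them were the flagellin receptor FLS2 (-1.09 ± 0.16) and FRK1 (-1.59 ± 0.16).

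Jasmonate genes were lower in 6 and higher in 2 of 19, with a median of -0.23 (camera adjusted p = 0.0457, and adjusted p = 0.807 with an estimated correlation). Rescaled, 10 were lower and 2 higher with median-of-ratios scaling and 9 and 2 with quantile normalization. Its members included ORA59 (-1.39 ± 0.12) and LOX2 (0.72 ± 0.054). This list call was lost without mutant control replicate 2 (adjusted p = 0.117), mutant control replicate 3 (adjusted p = 0.0685) or WT control replicate 3 (adjusted p = 0.0797), and with median-of-ratios scaling (adjusted p = 0.0812). Photosynthesis genes were lower in 12 and higher in 5 of 42, with a median of -0.16 (camera adjusted p = 0.0255, and adjusted p = 0.858 with an estimated correlation). Their own median turned from -0.10 to 0.0024 with quantile normalization, where 7 were lower and 7 higher, and 14 were lower and 2 higher with median-of-ratios scaling. Its call was lost without mutant control replicate 3 (adjusted p = 0.113). LHCB1.4 changed by -1.47 ± 0.16, uncertain because the near-identical LHCB1 copies can share reads. RBCS1B, a small subunit of Rubisco, changed by 0.96 ± 0.14.

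The other lists were not called by camera at control. Circadian clock genes were higher in 10 and lower in 10 of 20 (adjusted p = 0.468). The morning genes LHY (2.79 ± 0.087) and CCA1 (1.97 ± 0.078) were higher and PRR5 (-2.01 ± 0.078) and FKF1 (-1.87 ± 0.091) lower. Of the oxidative stress genes 8 were higher and 3 lower, and UPOX, a mitochondrial stress marker, went from 7.20 ± 0.331 to 70.6 ± 3.73 TPM. The oxidative stress median turned from 0.033 to -0.0041 with quantile normalization. Small heat shock proteins were higher in 4 and lower in 4 of 17, among them HSP23.5 (2.79 ± 0.14), a mitochondrial member. Their median of -0.17 and mean of 0.072 differed in sign. Heat shock transcription factors were higher in 7 and lower in 4, with a mean of -0.025 and a median that turned from 0.052 to -0.0035 with quantile normalization. Counts of higher and lower members were 1 and 4 for heat memory genes, 5 and 5 for the unfolded protein response of the endoplasmic reticulum (ER; median -0.038, mean 0.21, camera upward) and 3 and 4 for salicylic acid defence. Abscisic acid genes were higher in 11 and lower in 8, and their camera direction was down against a median of 0.24. Chlorophyll synthesis genes were higher in 6 and lower in 4, with a median that turned from 0.044 to -0.039 with median-of-ratios scaling. Further counts were 3 and 2 for senescence, 1 and 3 for flowering time and 5 and 2 for the cell cycle (median -0.0017, mean 0.021). They were 7 and 2 for microRNA biogenesis, 26 and 12 for microRNA targets and 3 and 1 for thermomorphogenesis (median -0.14, mean 0.059). Markers of roots were higher in 3 and lower in 6, of guard cells in 1 and 1, of vessels and phloem in 1 and 2 and of seeds in 0 and 0, and reference genes in 2 and 3. Adjusted over the list alone, the higher and lower counts were 16 and 2 for SR factors, 14 and 2 for large chaperones, 12 and 8 for abscisic acid and 3 and 12 for photosynthesis. They were 3 and 2 for the cell cycle, 28 and 13 for microRNA targets, 3 and 5 for root and 3 and 2 for vascular markers, and the same as over all genes for the rest. Ribosome genes made up 267 of the higher calls, out of 387 annotated (KEGG, one-sided Fisher's exact test, adjusted p = 2.88e-40), and spliceosome genes 224 of 338 (adjusted p = 1.44e-29). Among calls of at least 2-fold neither pathway was enriched (same test, adjusted p = 1 for each). The higher and lower counts became 4 and 5 for heat shock transcription factors, 2 and 6 for salicylic acid defence, 3 and 4 for senescence, 3 and 3 for the cell cycle, 3 and 4 for thermomorphogenesis and 1 and 3 for reference genes with median-of-ratios scaling.

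From control to 3 days, WT showed higher heat shock transcripts and lower light-harvesting transcripts. HSP21 (AT4G27670), a chloroplast small heat shock protein that persists after heat, was listed at 0.06, 0 and 0 TPM in the libraries of WT control and averaged 1629 ± 254 at 3 days. The cytosolic HSP17.6II rose from 0.86 ± 0.322 to 1681 ± 168 TPM and the chaperone HSP90.1 by 6.90 ± 0.10. All 42 measured photosynthesis genes fell, and LHCB2.3, an antenna protein of photosystem II, went from 1628 ± 52.0 to 3.62 ± 0.713 TPM. MYBL2, a repressor of anthocyanin synthesis, fell from 117 ± 8.76 to 1.36 ± 0.370 TPM.

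In the WT response 12339 genes rose and 5932 fell, 5875 and 2583 of them at least 2-fold, with an all-gene median of 0.39. The split was 8917 and 8878 with median-of-ratios scaling and 8965 and 8874 with quantile normalization. Ranked changes here and below follow the rule for named genes, which left out HSP17.6C (9.67 in WT). The largest increases were HSP21 (10.63 ± 0.16), HSP17.6II (9.83 ± 0.14), HSP22 (9.39 ± 0.11), HSP17.4A (9.29 ± 0.29), HSP17.7 (locus AT5G12030, 9.06 ± 0.27) and HSP23.6 (9.05 ± 0.10). In WT control HSP22 was listed at 0.06, 0 and 0.06 TPM and HSP17.4A at 0.55, 0 and 1.73. The largest decreases were LHCB2.3 (-8.47 ± 0.091), LHCB1.4 (-6.76 ± 0.16), MLP328 (-5.69 ± 0.13), MYBL2 (-5.66 ± 0.11), ATCTH (-5.25 ± 0.094) and AIR1 (-5.20 ± 0.16), and the 12 genes had adjusted p of 7.53e-11 or less. LHCB1.4 is uncertain for the reason given above.

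Small heat shock proteins rose in 16 of 17 members, with a median of 6.84 relative to all genes (camera adjusted p = 1.34e-05, and adjusted p = 0.208 with an estimated correlation). HSP15.4 was the exception (-1.02 ± 0.098). Heat memory genes rose in 14 of 14, with a median of 4.49 (camera adjusted p = 5.21e-06, and adjusted p = 0.208 with an estimated correlation). Large chaperones rose in 17 of 18, with a median of 2.63 (camera adjusted p = 2.37e-06, and adjusted p = 0.208 with an estimated correlation), led by ROF2 (7.35 ± 0.066). Heat shock transcription factors rose in 17 and fell in 3 of 21, with a median of 1.38 (camera adjusted p = 0.00448, and adjusted p = 0.208 with an estimated correlation). HSFA2, a factor that sustains the heat response, rose by 5.27 ± 0.13, the coactivator MBF1C, which is no HSF, by 5.13 ± 0.098, and HSFC1 fell (-0.78 ± 0.11). Of the 17 HSF genes alone, 13 rose and 3 fell. The ER unfolded protein response list rose in 12 of 14, with a median of 0.67 (camera adjusted p = 0.0029, and adjusted p = 0.383 with an estimated correlation). The ER co-chaperone ERDJ3A rose by 4.40 ± 0.069. Among splicing genes, 13 of 13 MAC and spliceosome core members rose, with a median of 0.65 (camera adjusted p = 0.0018, and adjusted p = 0.305 with an estimated correlation). PRL2 rose by 3.12 ± 0.082. SR splicing factors rose in 16 and fell in 3 of 20, with a median of 0.61 (camera adjusted p = 0.0396, and adjusted p = 0.33 with an estimated correlation), a call lost with median-of-ratios scaling (adjusted p = 0.14). Rising and falling SR members numbered 11 and 5 with median-of-ratios scaling and 12 and 5 with quantile normalization. SR45A rose by 3.49 ± 0.061 and SR30 by 3.49 ± 0.042. MicroRNA biogenesis genes rose in 11 of 11, with a median of 0.92 (camera adjusted p = 0.00224, and adjusted p = 0.208 with an estimated correlation). Among these was CPL1 (1.85 ± 0.045).

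On the lower side, photosynthesis had a median of -3.00 relative to all genes (camera adjusted p = 1.46e-24, and adjusted p = 0.208 with an estimated correlation). Chlorophyll synthesis genes fell in 15 of 16, with a median of -1.77 (camera adjusted p = 5.16e-10, and adjusted p = 0.208 with an estimated correlation). PORB, which reduces protochlorophyllide in light, fell from 1040.4 ± 48.9 to 125 ± 8.47 TPM. Carbon starvation genes fell in 10 of 11, with a median of -1.99 (camera adjusted p = 6.80e-06, and adjusted p = 0.208 with an estimated correlation). SEN1 (-4.37 ± 0.20) and TPS11 (-2.18 ± 0.12) fell too. Pattern-triggered immunity genes fell in 9 and rose in 1 of 15, with a median of -0.89 (camera adjusted p = 0.00224, and adjusted p = 0.305 with an estimated correlation). Among them were GSTF6 (-2.49 ± 0.26) and CYP81F2 (-2.22 ± 0.14). Root markers fell in 11 and rose in 4 of 19, with a median of -1.27 (camera adjusted p = 4.74e-04, and adjusted p = 0.278 with an estimated correlation). Of these markers 15 fell and none rose with median-of-ratios scaling, and 16 and none with quantile normalization. The iron transporter IRT1 (-4.73 ± 0.24) and the root beta-glucosidase PYK10 (-3.80 ± 0.15) fell, and IRT1 was listed at 0.1, 0.13 and 0 TPM in WT 3 days. Cell cycle genes rose in 9 and fell in 13 of 22, with a median of -1.31 (camera adjusted p = 0.0396, and adjusted p = 0.479 with an estimated correlation). That call was lost with median-of-ratios scaling (adjusted p = 0.227) and with a pseudocount of 0.1 (adjusted p = 0.0702). The mitotic cyclin CYCB1;2 fell (-2.75 ± 0.084) and the replication gene MCM4 rose (1.87 ± 0.071).

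For lists without a camera call in WT, members that rose and fell numbered 14 and 4 for salicylic acid defence (own median 0.41, and -0.019 with quantile normalization), 13 and 5 for jasmonate and 15 and 4 for abscisic acid. There were 14 and 3 for oxidative stress, 8 and 4 for senescence and 11 and 3 for anthocyanin. The numbers were 6 and 7 for glucosinolate and 23 and 22 for microRNA targets, with a downward camera direction. Their medians of 0.051 and 0.083 turned to -0.40 and -0.31 with median-of-ratios scaling. They were 13 and 5 for the clock, 2 and 4 for flowering time and 2 and 5 for thermomorphogenesis (own median 0.0098, mean -0.31, and median -0.34 with median-of-ratios scaling). Markers counted 2 and 4 for guard cell, 6 and 1 for vascular and 1 and 0 for seed markers (own median 0.34, and -0.11 with quantile normalization). Reference genes rose in 8 and fell in 3 (own median 0.31, and -0.14 with median-of-ratios scaling). The peroxidase APX2 (7.92 ± 0.061), the dehydration gene RD29B (4.59 ± 0.14) and PAP1, a regulator of anthocyanin synthesis (3.88 ± 0.23), all rose. APX2 was listed at 0.06, 0.06 and 0 TPM in WT control. Adjusted over the list alone, higher and lower counts were 18 and 0 for large chaperones, 18 and 3 for heat shock factors, 13 and 0 for the ER list and 14 and 4 for oxidative stress, and the same as over all genes for the others. Transposable element loci summed to 369 ± 9.54 TPM in WT control and 7211 ± 443 at 3 days, with 397 of 430 tested loci higher and 9 lower. Mitochondria-encoded genes summed to 207 ± 30.0 and 19824 ± 711 TPM. In KEGG, 278 of 338 spliceosome genes were among the higher calls (one-sided Fisher's exact test, adjusted p = 4.29e-25) and 22 of 26 antenna protein genes among the lower ones (adjusted p = 5.19e-07). Rising and falling members became 10 and 6 for salicylic acid defence, 13 and 9 for abscisic acid, 11 and 6 for oxidative stress, 6 and 5 for senescence, 8 and 4 for anthocyanin and 3 and 13 for glucosinolate genes with median-of-ratios scaling. In that setting they were 14 and 34 for microRNA targets, 9 and 7 for the clock, 2 and 6 for flowering time, 1 and 8 for thermomorphogenesis, 0 and 5 for guard cell markers and 4 and 5 for reference genes.

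**Figure D2:**
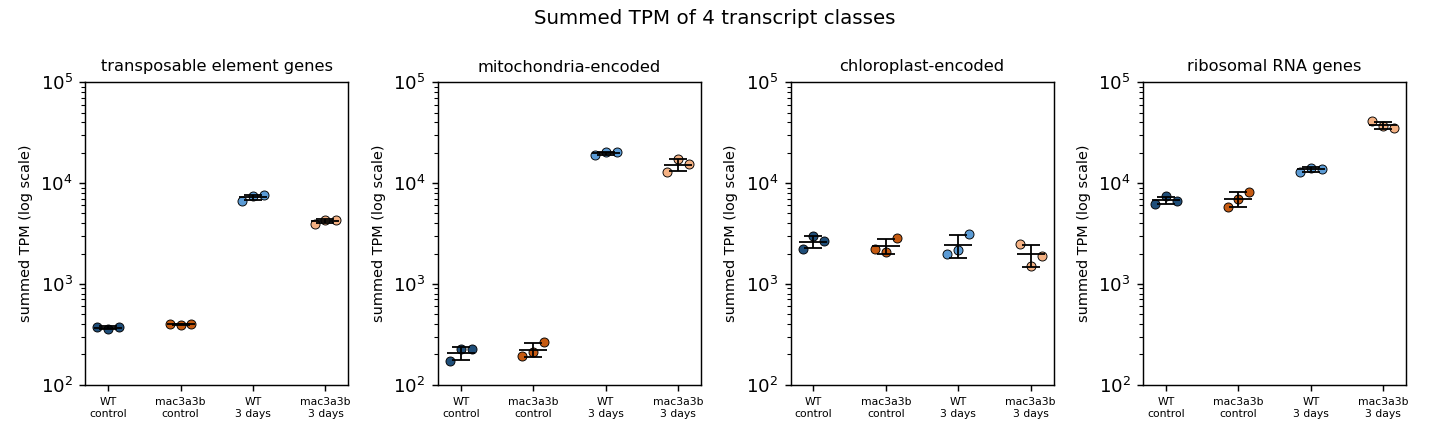
Summed TPM per library on a log axis of transposable element loci, mitochondrial genes, chloroplast genes and ribosomal RNA loci in the 4 groups (points, with bars of the mean ± SD of 3 libraries). Mitochondrial genes went from 222 ± 36.1 in mutant control to 15268 ± 2130 in mutant 3 days, while chloroplast genes stood at 2366 ± 408 and 1963 ± 491.

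In the mutant, the response combined higher heat shock protein and ER chaperone transcripts with lower light-harvesting, flavonoid and glucosinolate transcripts. HSP90.1 rose from 6 ± 0.374 to 1709.9 ± 145 TPM and HSP70-4 by 7.16 ± 0.068. BIP2, a lumenal ER chaperone whose near-identical copy BIP1 can share reads, rose from 101 ± 8.82 to 2195 ± 249.5 TPM, and ERDJ3A from 2.62 ± 0.165 to 452 ± 24.5. GUN4, which promotes magnesium chelatase in chlorophyll synthesis, fell from 244 ± 10.3 to 0.533 ± 0.176 TPM, and GSTU20 from 668 ± 30.0 to 0.58 ± 0.164. CYP79F1 fell from 144 ± 8.73 to 0.23 ± 0.138 TPM.

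In the mutant 8857 genes rose and 10438 fell, 4959 and 6693 at least 2-fold, with an all-gene median of -0.13. The split was 9725 and 9661 with median-of-ratios scaling and 10036 and 9196 with quantile normalization, where the median was 0.066. Here the rule for named genes left out HSP17.6C (9.22), HSP17.6B (8.39) and HSP17.8 (8.06). The largest increases were HSP17.4A (9.03 ± 0.29), HSP17.7 (9.0 ± 0.27), HSP17.6II (8.83 ± 0.14), HSP21 (8.66 ± 0.16), HSP22 (8.49 ± 0.11) and HSP90.1 (7.93 ± 0.10). In mutant control HSP22 was listed at 0, 0.06 and 0 TPM, HSP17.4A at 0, 0.61 and 0.23 and HSP21 at 0, 0 and 0.27. The largest decreases were LHCB2.3 (-10.35 ± 0.091), GSTU20 (-8.73 ± 0.070), LHCB1.1 (-8.56 ± 0.14, uncertain for the same reason as LHCB1.4), GASA6 (-7.93 ± 0.14), GER1 (-7.72 ± 0.095) and GUN4 (-7.33 ± 0.082), and the 12 genes had adjusted p of 4.03e-11 or less.

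Small heat shock proteins rose in 16 of 17, with a median of 7.63 relative to all genes (camera adjusted p = 1.08e-06, and adjusted p = 0.136 with an estimated correlation). Heat memory genes rose in 14 of 14, with 5.27 (camera adjusted p = 1.08e-06, and adjusted p = 0.183 with an estimated correlation). Large chaperones rose in 17 of 18, with 3.34 (camera adjusted p = 3.17e-08, and adjusted p = 0.219 with an estimated correlation). Heat shock transcription factors rose in 18 and fell in 2 of 21, with a median of 1.78 (camera adjusted p = 2.83e-05, and adjusted p = 0.136 with an estimated correlation). Leading members were DREB2C (5.76 ± 0.12), which is no HSF, and HSFA2 (5.58 ± 0.13), and of the 17 HSF genes 14 rose and 2 fell. ER unfolded protein response genes rose in 14 of 14, with a median of 3.27 (camera adjusted p = 3.18e-07, and adjusted p = 0.247 with an estimated correlation). MAC and spliceosome core genes rose in 12 and fell in 1 of 13, with a median of 1.56 (camera adjusted p = 6.02e-05, and adjusted p = 0.264 with an estimated correlation). PRL2 rose by 3.84 ± 0.082. Senescence genes rose in 9 and fell in 2 of 14, with a median of 1.09 (camera adjusted p = 0.0434, and adjusted p = 0.39 with an estimated correlation), a call lost with median-of-ratios scaling (adjusted p = 0.0547). The chlorophyll breakdown gene NYE2 rose by 2.91 ± 0.14. Salicylic acid defence genes rose in 14 and fell in 4 of 23, with a median of 0.62 (camera adjusted p = 0.0319, and adjusted p = 0.518 with an estimated correlation). Among them were SARD1 (4.50 ± 0.13) upward and PR5 (-2.39 ± 0.11) downward. MicroRNA biogenesis genes rose in 9 and fell in 2 of 11, with a median of 1.28 (camera adjusted p = 0.0177, and adjusted p = 0.308 with an estimated correlation). Here SE rose (1.48 ± 0.057) and AGO1 fell (-1.05 ± 0.039).

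SR splicing factors rose in 12 and fell in 5 of 20, with a median of 0.45 (camera adjusted p = 0.0488, and adjusted p = 0.377 with an estimated correlation). SCL30A fell (-1.41 ± 0.050). Their list call was lost without mutant control replicate 1 (adjusted p = 0.0604), mutant control replicate 3 (adjusted p = 0.0502) or mutant 3 days replicate 3 (adjusted p = 0.0563). Abscisic acid genes rose in 16 and fell in 8 of 26, with a median of 1.53 (camera adjusted p = 0.0434, and adjusted p = 0.485 with an estimated correlation). Rising and falling members numbered 16 and 4 with quantile normalization. Among them were RD29A (3.22 ± 0.080) and P5CS1 (-2.84 ± 0.12). The abscisic acid call was lost without mutant control replicate 3 (adjusted p = 0.0502) and with median-of-ratios scaling (adjusted p = 0.0564).

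Photosynthesis genes fell in all 42 of 42, with a median of -3.64 relative to all genes (camera adjusted p = 4.09e-12, and adjusted p = 0.326 with an estimated correlation). Chlorophyll synthesis genes fell in 16 of 16, with -2.90 (camera adjusted p = 1.08e-06, and adjusted p = 0.264 with an estimated correlation). Anthocyanin genes fell in 17 of 17, with a median of -2.74 (camera adjusted p = 3.90e-05, and adjusted p = 0.136 with an estimated correlation). DFR was listed at 0.1, 0 and 0.05 TPM in the libraries of mutant 3 days. Glucosinolate genes fell in 16 and rose in 1 of 20, with a median of -3.27 (camera adjusted p = 2.39e-04, and adjusted p = 0.377 with an estimated correlation). With median-of-ratios scaling 4 of these genes rose and 16 fell. Among these was MAM1 (-6.16 ± 0.095). Cell cycle genes fell in 15 and rose in 3 of 22, with a median of -1.56 (camera adjusted p = 0.0137, and adjusted p = 0.39 with an estimated correlation). Here CYCA1;1 (-4.21 ± 0.099) and HIK (-3.93 ± 0.084) fell. MicroRNA target genes fell in 46 and rose in 9 of 61, with a median of -0.81 (camera adjusted p = 0.00105, and adjusted p = 0.251 with an estimated correlation). GRF3 (-3.91 ± 0.077) was among them. Root markers fell in 17 and rose in 0 of 19, with a median of -1.64 (camera adjusted p = 5.83e-04, and adjusted p = 0.308 with an estimated correlation). Vascular markers fell in 7 of 7, with -2.10 (camera adjusted p = 0.00565, and adjusted p = 0.268 with an estimated correlation). Here the sucrose carrier SUC2 fell (-3.1 ± 0.12).

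Lists with no camera call in the mutant had rising and falling members of 5 and 8 for pattern-triggered immunity (own median -0.44, and 0.17 with quantile normalization), 4 and 9 for jasmonate and 10 and 10 for oxidative stress. The others had 6 and 2 for carbon starvation, 8 and 10 for the clock, 4 and 5 for flowering time, 2 and 7 for thermomorphogenesis, 2 and 6 for guard cell and 3 and 0 for seed markers. Reference genes counted 6 and 4 (own median 0.21, and -0.17 with quantile normalization). PIF4, a growth regulator at warm temperature (-3.48 ± 0.058), and the floral activator SOC1 (-3.87 ± 0.10) fell. Counts adjusted over the list alone were the same as over all genes except for the targeted genes. Transposable element loci summed to 396 ± 1.62 TPM in mutant control and 4189 ± 207 at 3 days, with 239 higher and 23 lower. In KEGG, 251 of 338 spliceosome genes (one-sided Fisher's exact test, adjusted p = 2.68e-37) and 229 of 339 genes of protein processing in the ER (adjusted p = 3.57e-24) were among the higher calls. Among the lower calls were 152 of 224 phenylpropanoid genes (adjusted p = 5.83e-07, same test). Thermomorphogenesis genes rose and fell in 4 and 7 with median-of-ratios scaling, and reference genes in 5 and 6 with quantile normalization.

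At 3 days the mutant differed from WT in lower photosynthesis, glucosinolate, flavonoid and vascular transcripts and higher ER chaperone transcripts. LHCA4, an antenna protein of photosystem I, stood at 862 ± 103 TPM in WT and 75.2 ± 1.02 in the mutant, and GUN4 at 54.7 ± 3.84 and 0.533 ± 0.176. CYP79F1 stood at 40.7 ± 1.17 and 0.23 ± 0.138 TPM, and the xylem protease XCP2 at 237 ± 34.7 and 7.85 ± 0.310. BIP2 stood at 219 ± 17.9 TPM in WT and 2195 ± 249.5 in the mutant, and HSP101, a cytosolic disaggregase needed for acquired heat tolerance, at 111 ± 7.39 and 264 ± 23.8. AATP1, an AAA-type ATPase, had 2.31 ± 0.0473 and 144 ± 29.7 TPM.

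Of all genes 5403 were higher and 13185 lower in mutant 3 days than in WT 3 days, 1820 and 7349 at least 2-fold, with a median of all genes of -0.51. The split was 8634 and 9553 with median-of-ratios scaling and 9050 and 8468 with quantile normalization. The largest increases were AATP1 (5.44 ± 0.13), PP2-B11 (4.56 ± 0.095), NAC074 (4.38 ± 0.17), CYP71A23 (4.15 ± 0.10), ECT10 (4.09 ± 0.16) and TPS11 (3.97 ± 0.12). The largest decreases were GER3 (-6.02 ± 0.10), GSTU20 (-5.94 ± 0.070), IPMI1 (-5.41 ± 0.084), CYP81F4 (-5.32 ± 0.13), TLL1 (-5.27 ± 0.13) and GUN4 (-5.19 ± 0.082), and all 12 had adjusted p of 5.8e-10 or less. IPMI1, a subunit of an isomerase of methionine chain elongation, was listed at 0.11, 0 and 0 TPM in the libraries of mutant 3 days.

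ER unfolded protein response genes were higher in 14 of 14, with a median of 2.77 relative to all genes (camera adjusted p = 5.87e-11, and adjusted p = 0.354 with an estimated correlation). Leading members were BIP3 (3.78 ± 0.18) and BIP2 (3.32 ± 0.089). Large chaperones were higher in 16 and lower in 2 of 18, with a median of 1.3 (camera adjusted p = 5.36e-07, and adjusted p = 0.354 with an estimated correlation). HSP90.2 (1.67 ± 0.064) and HSC70-3 (1.62 ± 0.047) were higher and ROF2 was lower (-1.31 ± 0.066). MAC and spliceosome core genes were higher in 11 and lower in 1 of 13, with a median of 1.4 (camera adjusted p = 5.10e-06, and adjusted p = 0.354 with an estimated correlation). Leading members were ISY1 (1.62 ± 0.047) and MAC5A (1.42 ± 0.064). Heat shock transcription factors were higher in 10 and lower in 7 of 21, with a median of 0.75 (camera adjusted p = 0.0151, and adjusted p = 0.354 with an estimated correlation). The higher and lower factors numbered 15 and 2 with median-of-ratios scaling and 15 and 3 with quantile normalization. The list ranged from DREB2B (1.73 ± 0.094) to HSFC1 (-1.25 ± 0.11), and its 3 highest members were the DREB2 genes, which are not HSF genes. Of the 17 HSF genes, 7 were higher and 6 lower, against 12 and 1 with median-of-ratios scaling and 12 and 2 with quantile normalization, and the highest was HSFA4A (0.65, chosen after its values were seen). Salicylic acid defence genes were higher in 10 and lower in 6 of 23, with a median of 0.84 (camera adjusted p = 0.0151, and adjusted p = 0.688 with an estimated correlation). Here the counts became 14 and 6 with median-of-ratios scaling and 16 and 5 with quantile normalization. Among them were PBS3 (3.24 ± 0.20) and NPR4 (-2.09 ± 0.11). Senescence genes were higher in 9 and lower in 2 of 14, with a median of 1.19 (camera adjusted p = 0.00204, and adjusted p = 0.354 with an estimated correlation). NYE2 (2.38 ± 0.14) was among them. Carbon starvation genes were higher in 8 and lower in 2 of 11, with 1.42 (camera adjusted p = 8.61e-04, and adjusted p = 0.354 with an estimated correlation). Their counts became 8 and 1 with median-of-ratios scaling and 8 and 0 with quantile normalization. DIN2 (3.64 ± 0.17) was among them.

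Photosynthesis genes were lower in 34 and higher in none of 42, with a median of -0.78 (camera adjusted p = 0.00453, and adjusted p = 0.757 with an estimated correlation). With median-of-ratios scaling 25 were lower and 10 higher, with their own median going from -1.29 to -0.73, and with quantile normalization 35 and 1. Chlorophyll synthesis genes were lower in 15 of 16, with -1.21 (camera adjusted p = 0.00108, and adjusted p = 0.573 with an estimated correlation). Beside these lists, ribosomal RNA loci summed higher (see above), root markers were lower in 16 of 19 and guard cell markers in 6 of 8. With quantile normalization 10 root markers were lower and 1 higher, with their own median going from -1.22 to -0.39, and 4 guard cell markers were lower and 2 higher. Anthocyanin genes were lower in 16 of 17, with a median of -1.63 (camera adjusted p = 0.00276, and adjusted p = 0.354 with an estimated correlation). LDOX was lower (-3.34 ± 0.17). Glucosinolate genes were lower in 18 of 20, with -2.04 (camera adjusted p = 0.00204, and adjusted p = 0.573 with an estimated correlation). Higher and lower glucosinolate genes numbered 2 and 16 with median-of-ratios scaling. CYP83A1 was lower too (-4.93 ± 0.16). Cell cycle genes were lower in 19 and higher in 1 of 22, with a median of -0.64 (camera adjusted p = 0.00802, and adjusted p = 0.573 with an estimated correlation). Higher and lower members became 3 and 17 with median-of-ratios scaling and 4 and 12 with quantile normalization. Among these was the cyclin CYCD3;1 (-3.91 ± 0.070). Vascular markers were lower in 7 of 7, with a median of -2.46 (camera adjusted p = 0.00802, and adjusted p = 0.354 with an estimated correlation). Among them were XCP2 (-4.74 ± 0.11) and XCP1 (-3.30 ± 0.12).

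The remaining lists were not called at 3 days. Small heat shock proteins were higher in 3 and lower in 11 of 17 (adjusted p = 0.647), with HSP26.5 higher (1.01 ± 0.20) and HSP15.7 lower (-1.89 ± 0.17). Heat memory genes were higher in 4 and lower in 10 (adjusted p = 0.675), with HSP101 higher (1.24 ± 0.083) and FTSH6 lower (-2.72 ± 0.16). Jasmonate genes counted 1 higher and 14 lower, including the synthesis enzyme AOS (-3.45 ± 0.083), and microRNA targets 9 and 46, including SPL2 (-3.44 ± 0.13). The list medians of SR factors (5 higher, 10 lower), pattern-triggered immunity (3 and 7), abscisic acid (10 and 11), oxidative stress (8 and 11), the clock (4 and 12), microRNA biogenesis (4 and 4) and reference genes (3 and 6) were below 0 as deposited and at 0.35, 0.18, 0.42, 0.044, 0.21, 0.53 and 0.18 with median-of-ratios scaling. That of flowering time (4 higher, 6 lower) turned from -0.54 to 0.037 with quantile normalization. In these 8 lists the camera direction was up, except for the clock, and the mean of the abscisic acid list was 0.023. Thermomorphogenesis genes counted 3 and 7 and seed markers 2 and 1. Counts adjusted over the list alone were 8 and 12 for oxidative stress and 3 and 9 for thermomorphogenesis, and the same as over all genes otherwise. Transposable element loci were higher in 45 and lower in 345 of 430. In KEGG, 187 of 338 spliceosome genes (one-sided Fisher's exact test, adjusted p = 3.36e-29), 160 of 339 genes of protein processing in the ER (adjusted p = 9.77e-16) and 55 of 80 proteasome genes (adjusted p = 6.56e-14) were higher. Of 59 glucosinolate genes, 51 were lower (adjusted p = 1.21e-04, same test). Higher and lower members became 12 and 3 for SR factors, 5 and 8 for small heat shock proteins, 6 and 8 for heat memory genes, 7 and 4 for pattern-triggered immunity, 3 and 14 for jasmonate and 14 and 9 for abscisic acid with median-of-ratios scaling. In that setting they were 10 and 8 for oxidative stress, 10 and 7 for the clock, 4 and 4 for flowering time, 7 and 2 for microRNA biogenesis, 16 and 37 for microRNA targets, 3 and 5 for thermomorphogenesis, 2 and 6 for guard cell markers and 5 and 1 for reference genes.

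**Figure D3:**
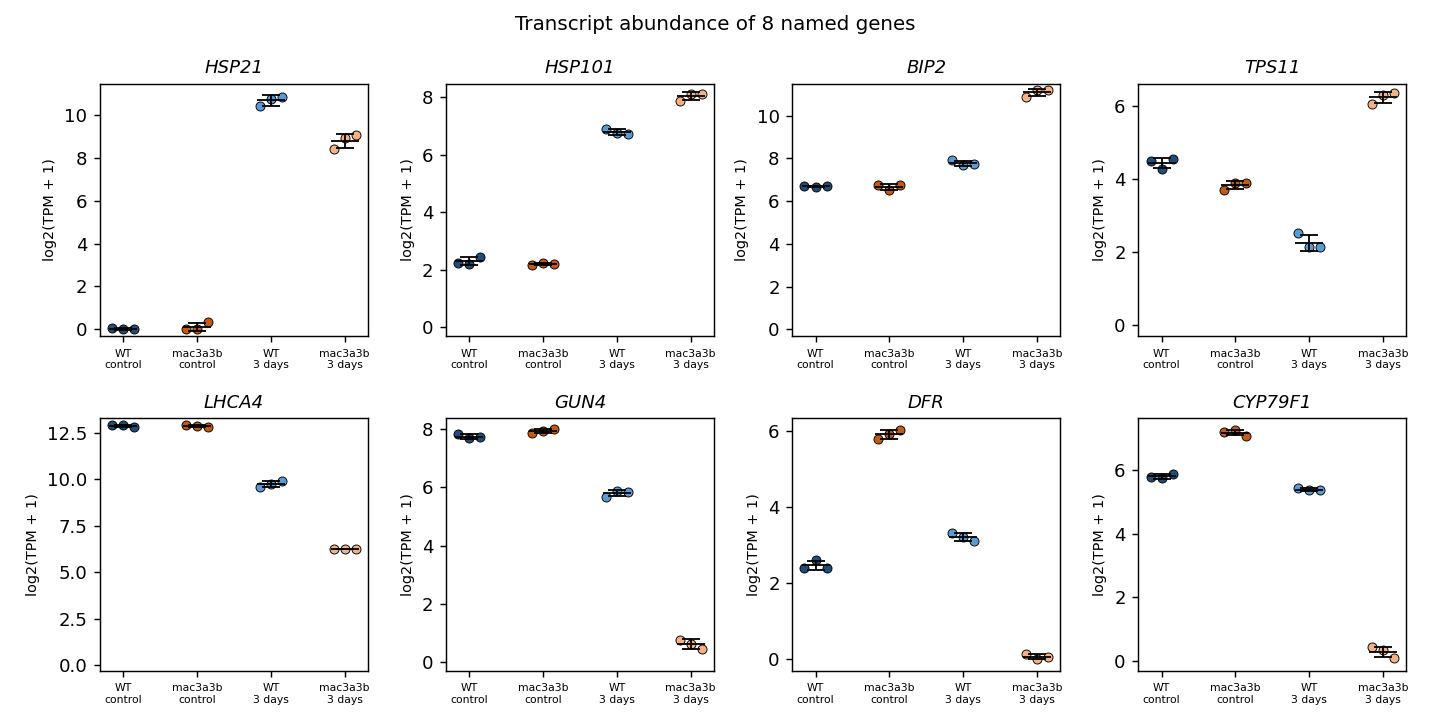
Expression as log2(TPM + 1) of HSP21, HSP101, BIP2, TPS11, LHCA4, GUN4, DFR and CYP79F1 in each of the 12 libraries by group (points, with bars of the mean ± SD of 3 libraries on that scale). DFR averaged 60.0 ± 4.84 TPM in mutant control and was listed at 0.1, 0 and 0.05 in the libraries of mutant 3 days, and TPS11 averaged 3.80 ± 0.751 in WT 3 days and 74.0 ± 8.11 in mutant 3 days.

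The interaction contrast tested the difference between the mutant and WT responses. Of 11 carbon starvation genes, 10 had a higher response in the mutant and none a lower one. TPS11, a trehalose phosphate synthase homologue, went from 20.6 ± 2.00 to 3.80 ± 0.751 TPM in WT and from 13.2 ± 1.03 to 74.0 ± 8.11 in the mutant. The sugar transporter MSS1 went from 14.3 ± 1.77 to 10.8 ± 3.05 TPM in WT and from 7.16 ± 1.35 to 109 ± 10.7 in the mutant. GBSS1, which makes amylose in starch granules, went from 21.0 ± 0.939 to 62.6 ± 5.19 TPM in WT and from 89.9 ± 3.88 to 1.45 ± 0.237 in the mutant. PDIL1-1, an ER foldase, went from 104 ± 4.22 to 104 ± 3.05 and from 64.3 ± 1.96 to 516 ± 46.9 TPM.

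The response was higher in the mutant for 4620 genes and lower for 12657, 1825 and 7613 of them at least 2-fold, with a median of all genes of -0.55. The split was 8262 and 8491 with median-of-ratios scaling and 8319 and 7800 with quantile normalization. The largest positive differences were AATP1 (5.10 ± 0.19), PP2-B11 (4.78 ± 0.13), U1.7, TPS11 (4.58 ± 0.17), MSS1 (4.16 ± 0.25) and the dehydrin LTI30 (4.03 ± 0.17). The value of U1.7 (4.73 ± 1.91, adjusted p = 0.0403) rests on single libraries. The transcript was listed at 0, 32.88 and 0 TPM in WT control, 19.51, 0 and 18.64 in WT 3 days and 0 in all libraries of mutant control. The call was lost without WT control replicate 2 (3.04, adjusted p = 0.0696), WT 3 days replicate 2 (3.29, adjusted p = 0.0908) or any 1 of the 6 mutant libraries (adjusted p from 0.0536 to 0.0753). It was also lost with a pseudocount of 0.1 (6.96, adjusted p = 0.0725). The largest negative differences were IPMI1 (-6.83 ± 0.12), GBSS1 (-6.75 ± 0.11), DFR (-6.61 ± 0.13), TLL1 (-6.49 ± 0.19), CYP79F1 (-6.46 ± 0.11) and GSTU20 (-6.25 ± 0.10), with adjusted p of 2.29e-10 or less.

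Carbon starvation had a median of 3.33 relative to all genes (camera adjusted p = 1.20e-07, and adjusted p = 0.204 with an estimated correlation). ER unfolded protein response genes were higher in 13 and lower in 1 of 14, with 2.7 (camera adjusted p = 1.44e-10, and adjusted p = 0.204 with an estimated correlation). The transcription factor NAC103 was the lower one (-1.40 ± 0.11). Large chaperones were higher in 12 and lower in 4 of 18, with 1.03 (camera adjusted p = 4.02e-04, and adjusted p = 0.467 with an estimated correlation). Their counts were 15 and 1 with median-of-ratios scaling and 11 and 4 with quantile normalization. They ranged from HSP101 (1.34 ± 0.12) to CLPB3 (-2.23 ± 0.077). MAC and spliceosome core genes were higher in 9 and lower in 3 of 13, with 0.92 (camera adjusted p = 0.0028, and adjusted p = 0.467 with an estimated correlation). The core members numbered 12 and 1 with median-of-ratios scaling and 8 and 2 with quantile normalization. They ranged from ISY1 (1.26 ± 0.067) to PRL1 (-0.89 ± 0.069). Heat shock transcription factors were higher in 7 and lower in 5 of 21, with 0.74 (camera adjusted p = 0.0118, and adjusted p = 0.467 with an estimated correlation). Of these factors, higher and lower ones numbered 14 and 1 with median-of-ratios scaling and 14 and 2 with quantile normalization. DREB2A (1.52 ± 0.18), which is no HSF, was among them, and of the 17 HSF genes 4 were higher and 4 lower, against 11 and 1 with either scaling. Salicylic acid defence genes were higher in 9 and lower in 5 of 23, with 0.85 (camera adjusted p = 0.0043, and adjusted p = 0.477 with an estimated correlation). Counts of defence genes were 16 and 3 with median-of-ratios scaling and 17 and 3 with quantile normalization. PBS3 (2.90 ± 0.28) was among them. Pattern-triggered immunity genes were higher in 8 and lower in 3 of 15, with 1.01 (camera adjusted p = 0.00713, and adjusted p = 0.467 with an estimated correlation). For immunity genes the counts were 10 and 2 with median-of-ratios scaling and 12 and 1 with quantile normalization. WRKY33 (2.02 ± 0.20) was among them. Senescence genes were higher in 8 and lower in 3 of 14, with 1.34 (camera adjusted p = 0.0028, and adjusted p = 0.467 with an estimated correlation). They share SEN1 (4.00 ± 0.29) with carbon starvation.

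Anthocyanin genes were lower in 16 and higher in 1 of 17, with a median of -2.71 relative to all genes (camera adjusted p = 4.24e-04, and adjusted p = 0.204 with an estimated correlation). Glucosinolate genes were lower in 18 and higher in 2 of 20, with -3.04 (camera adjusted p = 4.62e-04, and adjusted p = 0.467 with an estimated correlation). Chlorophyll synthesis genes were lower in 15 and higher in 1 of 16, with -1.21 (camera adjusted p = 0.0043, and adjusted p = 0.477 with an estimated correlation). CHLH (-2.95 ± 0.14) was among them. Vascular markers were lower in 7 of 7, with -2.36 (camera adjusted p = 0.00727, and adjusted p = 0.467 with an estimated correlation). IRX1 (-3.25 ± 0.16) was among them. Cell cycle genes were lower in 19 and higher in 1 of 22, with -0.68 (camera adjusted p = 0.015, and adjusted p = 0.477 with an estimated correlation). Higher and lower ones numbered 4 and 16 with median-of-ratios scaling and 4 and 12 with quantile normalization. CYCD3;1 (-3.94 ± 0.099) was among them. MicroRNA targets were lower in 44 and higher in 4 of 61, with -0.47 (camera adjusted p = 0.0232, and adjusted p = 0.467 with an estimated correlation). Targets with a higher and a lower response numbered 12 and 34 with median-of-ratios scaling and 16 and 30 with quantile normalization. SPL2 (-4.3 ± 0.18) was among them. Photosynthesis genes were lower in 29 and higher in 2 of 42, with -0.74 (camera adjusted p = 0.0367, and adjusted p = 0.779 with an estimated correlation). With median-of-ratios scaling 22 were lower and 11 higher, with their own median going from -1.30 to -0.65, and with quantile normalization 34 and 2. LHCA4 (-3.47 ± 0.11) was among them. Its list call was lost without mutant 3 days replicate 1 (adjusted p = 0.0805) or WT 3 days replicate 3 (adjusted p = 0.0541) and with median-of-ratios scaling (adjusted p = 0.0666).

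Without a camera call, higher and lower members numbered 2 and 14 for SR factors (2 and 15 adjusted over the list alone), 3 and 9 for small heat shock proteins, 2 and 9 for heat memory genes and 3 and 13 for jasmonate. The next were 11 and 13 for abscisic acid, 4 and 14 for oxidative stress, 7 and 13 for the clock and 5 and 4 for flowering time. They numbered 2 and 6 for microRNA biogenesis, 2 and 6 for thermomorphogenesis, 1 and 13 for root, 0 and 6 for guard cell and 1 and 1 for seed markers and 4 and 5 for reference genes, and list-alone adjustment changed no other count. Own medians of SR factors, abscisic acid and microRNA biogenesis turned from -0.54, -0.30 and -0.28 to 0.11, 0.28 and 0.32 with median-of-ratios scaling, and that of seed markers from -0.078 to 0.12. That of reference genes turned from 0.12 to -0.16 with quantile normalization. The clock median was -0.77 against an upward camera direction, and median and mean differed in sign for abscisic acid (mean 0.0022) and reference genes (mean -0.11). In KEGG, 142 of 339 genes of protein processing in the ER (one-sided Fisher's exact test, adjusted p = 4.46e-15) and 53 of 80 proteasome genes (adjusted p = 3.68e-15) had a higher response in the mutant. Of 70 aminoacyl-tRNA genes, 59 had a lower one (adjusted p = 2.19e-04, same test). The proteasome call was lost among calls of at least 2-fold (same test, adjusted p = 0.106). Higher and lower members became 8 and 8 for SR factors, 5 and 6 for small heat shock proteins, 5 and 4 for heat memory genes, 12 and 8 for abscisic acid, 8 and 9 for the clock and 5 and 3 for flowering time with median-of-ratios scaling. In that setting they were 7 and 3 for microRNA biogenesis, 5 and 6 for thermomorphogenesis, 2 and 5 for guard cell markers and 6 and 2 for reference genes, and with quantile normalization 5 and 10 for jasmonate and 3 and 10 for root markers.

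**Figure D4:**
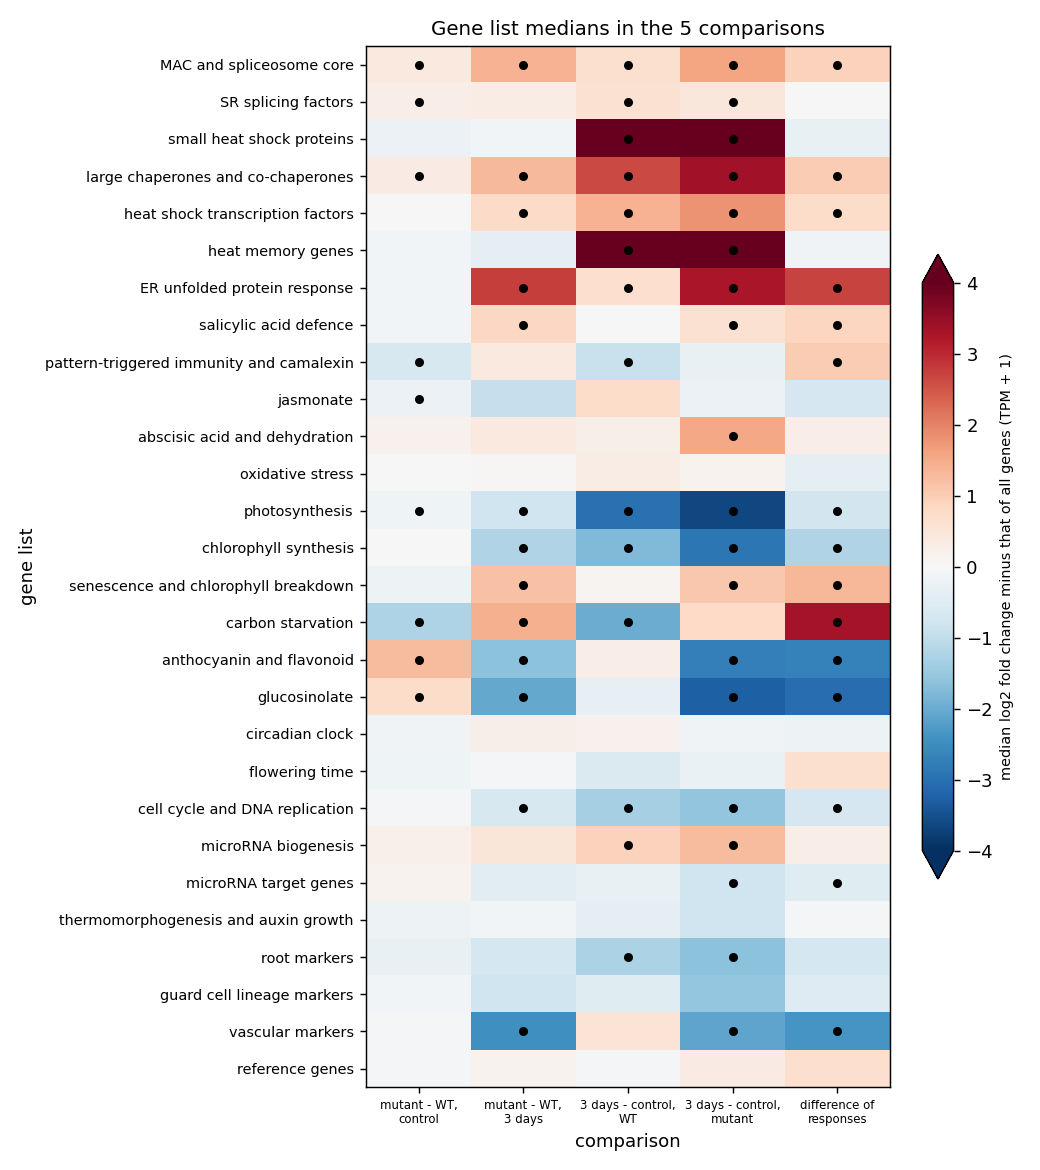
Heat map of the median log2 fold change of each of 28 gene lists (rows) minus the median of all genes, in the 5 comparisons (columns), with colours from -4 to 4 and dots for a camera adjusted p under 0.05. The ER unfolded protein response list reads 2.77 and glucosinolate -2.04 in mutant against WT at 3 days, and the own medians of 23 pairs of list and comparison change sign with median-of-ratios scaling or quantile normalization.

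The last measure was shared direction between comparisons. Over 22462 genes, which are not independent replicates, the log2 fold changes from control to 3 days in WT and in the mutant correlated with r = 0.715, with a slope of 0.942. Of 16056 genes called in both responses, 7589 rose in both, against 4865 if the calls were independent, 5183 fell in both, against 2757, and 3284 went opposite ways. The genotype differences at control and at 3 days correlated with r = 0.112. Of 9465 genes called in both, 2309 were higher in both, against 1636 if independent, 3041 lower in both, against 2532, and 4115 opposite. These pairs of comparisons share no library.

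**Figure D5:**
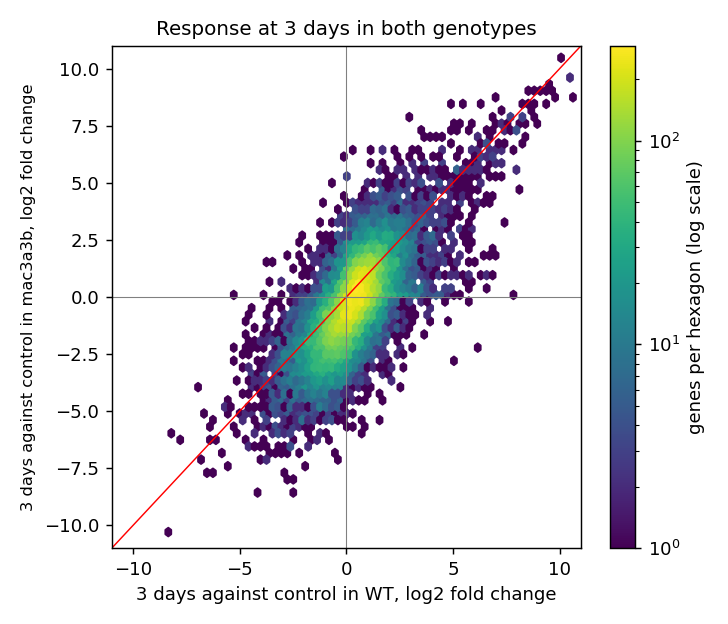
Log2 fold change from control to 3 days in WT (horizontal axis) and in the mutant (vertical axis) of 22462 genes, as hexagons coloured by the number of genes on a log scale, with the line of equality in red. Of genes called in both responses, 79.5% share direction (r = 0.715 across genes).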

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

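The tests of an even floor of reads and of scaling for transposable elements, all tests for mitochondrial transcripts, and the tests of scaling and of shoot tissue for photosynthesis and ER genes were chosen only after the result was seen, while the splits of the samples, the first test of genomic DNA and the tests of 1 element family and of gene length were chosen before.

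A test of the difference between the WT and mutant responses called 17277 genes. Of 100 drawn regroupings of genotype within each sampling point 1, the real one, called as many, and the highest of the others called 14832. Regroupings put libraries of distinct groups together, which widens the spread and lowers the calls from the start. They therefore say little about chance, and cannot tell genotype from a difference between cultures. The comparisons of 3 against 3 libraries have 10 splits each, of which 1, the real one, reached the real number, too few for a share under 0.05. The real split called 11116 genes and the highest other 5 for mutant against WT at control, 18588 and 3 at 3 days, 18271 and 1 for the WT response and 19295 and 3 for the mutant response.

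The same test of the difference gave list medians, mutant minus WT response, of 0.37 for MAC and spliceosome core, 0.47 for large chaperones, 0.18 for heat shock transcription factors, 2.15 for the ER unfolded protein response, 0.29 for salicylic acid defence, 0.46 for pattern-triggered immunity, 0.78 for senescence and 2.77 for carbon starvation. The medians were -1.30 for photosynthesis, -1.76 for chlorophyll synthesis, -3.26 for anthocyanin, -3.59 for glucosinolate, -1.23 for cell cycle, -1.02 for microRNA targets and -2.91 for vascular markers, and these 15 lists lost their camera call with an estimated correlation. These medians hold the shift of all genes (-0.55), and median-of-ratios scaling moved 10 of them by over 1.5 times. They were then 0.99 for MAC and spliceosome core, 1.11 for large chaperones, 0.66 for heat shock transcription factors, 0.83 for salicylic acid defence, 1.07 for pattern-triggered immunity and 1.36 for senescence, and -0.65 for photosynthesis, -1.13 for chlorophyll synthesis, -0.68 for cell cycle and -0.55 for microRNA targets. With quantile normalization 5 moved as much, to 0.54 for heat shock transcription factors, 1.05 for salicylic acid defence, 1.17 for pattern-triggered immunity, -0.60 for cell cycle and -0.36 for microRNA targets. Single genes with a higher response in the mutant were AATP1 (5.10), PP2-B11 (4.78), U1.7 (4.73), TPS11 (4.58), MSS1 (4.16) and LTI30 (4.03). The U1.7 call was lost without 1 of several libraries or with a pseudocount of 0.1, as given above. A lower response was called for IPMI1 (-6.83), GBSS1 (-6.75), DFR (-6.61), TLL1 (-6.49), CYP79F1 (-6.46) and GSTU20 (-6.25). Of 238 other named genes, chosen from these data, 209 differed too, against 76.9% of all genes.

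Transposable element loci were 19.6-fold higher at 3 days in WT and 10.6-fold in the mutant in summed TPM, while the largest ratio of median-of-ratios factors between libraries was 1.53, so scaling of TPM cannot be the whole cause. Among loci listed at 0 in all control libraries, 33.4% of elements and 19.4% of coding genes were above 0 in WT 3 days (ratio 1.72), and 24.5% and 21.9% in mutant 3 days (ratio 1.12), which left genomic DNA open in the mutant. A second test was therefore added: of these loci with at least 1000 bases (2163 elements and 1202 coding genes), the 5% highest held at least 87.5% of the TPM in either class and genotype, which argues against an even floor of reads, while genomic DNA that is not even remains a candidate source. The 10 highest loci held 46.1 ± 2.16% of the element TPM in mutant 3 days and 28.8 ± 0.313% in WT 3 days, which argues against 10 loci as the whole class but leaves open reads that RSEM spread over more copies of a family. Release of silenced elements after heat and overlap with loci AT2G07 (below) stay untested hypotheses.

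Mitochondria-encoded transcripts were 95.7-fold higher at 3 days in WT and 68.7-fold in the mutant in summed TPM. Less complete enrichment of polyadenylated RNA would raise chloroplast-encoded transcripts too, but their sum at 3 days was at most 0.93 times that of control. This argues against it as the whole cause unless chloroplast RNA itself fell about as much, which was not tested. Ribosomal RNA loci were 2.03-fold higher at 3 days in WT and 5.41-fold in the mutant, which goes with less complete enrichment, so a part of the rise may come from it. Loci AT2G07, a region of chromosome 2 that carries a copy of the mitochondrial genome, were at least 27.3-fold higher, and reads of the nuclear copy and of the mitochondrial genome cannot be told apart, because TPM does not show how shared reads were assigned. A change of mitochondrial RNA after heat stays open, untested.

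Photosynthesis genes were lower and ER chaperones higher in the mutant at 3 days. With median-of-ratios scaling 25 photosynthesis genes were lower and 10 higher, against 34 and none before, but the list median nearer 0 was still -0.73, which argues against scaling as the whole cause. A lower share of shoot tissue would raise root markers, whose median lay at -0.71 relative to all genes (quartiles -1.28 and -0.070), but with quantile normalization at -0.43 (quartiles -1.16 and 0.079, with 13 of 19 markers below all genes), so it stays open. Loss of long transcripts by RNA breakdown stays open, because the trend with gene length was nearly flat (medians of -0.44, -0.53, -0.57 and -0.49 in 4 groups of genes from the shortest to the longest), and its removal, which left at least 100.1% of the difference of either list from all genes, moved nothing. A slower recovery of the mutant may underlie the pattern as a hypothesis, since these data do not separate it from damage or death of the plants.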

How the results depend on the processing

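Only the removal of organelle, transposable element, ribosomal RNA and AT2G07 loci was chosen after seeing the data. It called 11023, 18140, 17905, 18944 and 16810 genes for mutant against WT at control and 3 days, WT and mutant responses and their difference. The main numbers of 11116, 18588, 18271, 19295 and 17277 ranged, across the other alternatives, over 9266 to 12169, 13746 to 20698, 13542 to 20373, 14290 to 21280 and 12920 to 18592, and over 9841 to 10131, 18079 to 18387, 17675 to 17869, 18872 to 19136 and 16844 to 17256 without single libraries. With the replicate number as a block the counts were 10958, 18530, 18253, 19224 and 17199, and the numbers do not pair the libraries, since residuals of 18 same-numbered pairs correlated between -0.0961 and 0.0772. Scaling moved directions more than totals: for the mutant against WT at 3 days, higher calls went from 5403 to 8634 (median-of-ratios) or 9050 (quantile) and lower calls from 13185 to 8468 (quantile), and for the difference of responses from 4620 to 8262 or 8319 and from 12657 to 7800. Of 140 list tests, 70 were called by camera, 69 with median-of-ratios scaling, 67 with the block, 120 by fry, 0 with an estimated correlation and 66 to 70 without single libraries. With the block the calls lost were jasmonate at control (adjusted p = 0.0586) and SR factors and abscisic acid in the mutant response (0.053 each), and among named genes U1.7 in the difference (0.0659). With fry, which asks another question, they were photosynthesis at control (0.39) and cell cycle in the WT response (0.399). Of 503 called values of named genes, 489 to 502 kept call and direction in other settings. Without single libraries 493 to 500 did, counting those not refitted as kept. With median-of-ratios scaling 5 reversed and the cause was not tested: the WT responses of FAMA (-0.15), KAT1 (-0.063) and PIF3 (-0.033), PRL1 in mutant against WT at 3 days (0.13) and the difference of GFA1 (0.26), of which only GFA1 passed there (adjusted p = 0.00756, against 0.0602 to 0.725 for the others). Enriched pathways went from 213 to 157 with 2-fold calls, of which 114 were enriched in both, and at control 0 of 15 higher and 3 of 26 lower pathways were. The correlation of genotype differences went from 0.112 to between 0.118 and 0.124. TPM keeps no depth, so what depth limits is unknown.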

Other observations

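The rescaled values of PR2, PR5, CAT2 and APX1 were added after the results were seen. The genes come from the rule for named genes, except PR2, CAT2 and APX1, but which of them are described here was chosen with their values known. Single stress genes differed between genotypes in both directions, and the differences given had adjusted p of 7e-06 or less unless another value is given. The pathogenesis-related gene PR1 was listed at 0, 0 and 0.08 TPM in the libraries of WT control and at 0 in all libraries of mutant control, and averaged 0.353 ± 0.170 TPM in WT 3 days and 19.5 ± 13.1 in mutant 3 days, with a genotype difference at 3 days of 3.74 ± 0.32 (adjusted p = 3.85e-07). PR1 stood at 34.4, 10.24 and 13.73 TPM in the mutant 3 days libraries, and without replicate 1 the mean was 12 TPM and the difference 3.26 (adjusted p = 5.77e-09). The related genes PR2 (-1.23, adjusted p = 3.80e-04) and PR5 (-1.07) were lower in mutant 3 days, PR2 being listed at 0.26, 0.05 and 0 TPM there, and with quantile normalization PR2 stood at -0.58 (adjusted p = 0.0398) and PR5 at -0.24 (adjusted p = 0.1). Dehydration genes went both ways. RD29A averaged 26.0 ± 3.09 TPM in WT 3 days and 159 ± 3.6 in mutant 3 days (2.58 ± 0.080), and LTI30 averaged 11.8 ± 1.03 and 76.9 ± 7.39 (2.61 ± 0.12), while RD29B averaged 27.3 ± 1.45 and 4.66 ± 0.219 (-2.32 ± 0.14). Of the enzymes that remove hydrogen peroxide, the catalase gene CAT1 was higher in mutant 3 days (145 ± 12.2 against 41.3 ± 0.872 TPM in WT) and the peroxidase gene APX2 lower (49.6 ± 2.75 against 250.3 ± 2.89). The catalase gene CAT3 was lower too (298 ± 31.3 against 1737 ± 148 TPM). CAT2 (-0.26, adjusted p = 0.00533) and APX1 (-0.53, adjusted p = 1.56e-05) were lower as deposited and at 0.30 (adjusted p = 0.00379) and 0.030 (adjusted p = 0.692) with median-of-ratios scaling. The zinc finger gene ZAT12 averaged 30.8 ± 4.44 TPM in WT 3 days and 121 ± 6.32 in mutant 3 days. UPOX responded less in the mutant (-2.50 ± 0.078, adjusted p = 3.38e-10), from a control level of 70.6 ± 3.73 TPM against 7.20 ± 0.331 in WT.

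In the clock, LHY averaged 4.16 ± 0.508 TPM in WT control, 9.32 ± 0.453 in WT 3 days, 34.5 ± 1.13 in mutant control and 8.26 ± 0.858 in mutant 3 days, and its response differed between genotypes by -2.95 ± 0.12 (adjusted p = 2.08e-09). RVE8, of the same gene family, differed by -4.22 ± 0.23. The evening gene LUX (1.85 ± 0.16) and PRR5 (2.85 ± 0.11) differed the other way. The hours of sampling are not given in the sources. Among flowering genes, MAF4, a relative of the repressor FLC, rose from 5.25 ± 1.14 to 12.3 ± 1.5 TPM in WT and from 7.23 ± 0.414 to 61.7 ± 5.68 in the mutant, with a difference of responses of 1.82 ± 0.18, while SOC1 differed by -1.70 ± 0.14. Transcripts with assembler identifiers and no locus (67) summed to 134 ± 5.53 TPM in WT control, 849 ± 67.9 in WT 3 days, 145 ± 4.25 in mutant control and 231 ± 36.0 in mutant 3 days.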
